A study of Mus musculus with 8 samples.

How the data were processed

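Gene expression was measured by RNA sequencing in alveolar bone, the part of the jaw that holds the teeth, of 12-week-old mice, 6 days after the right upper incisor had been removed. The labels place 3 samples in a control group, described as wild type, and 5 samples in a group called sh-Dlx3, described as having Dlx3 inhibited. They do not state how the inhibition was delivered, what the controls received, or whether samples came from separate animals. P-values therefore measure the spread between these samples, part of which may be technical. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the BGISEQ-500 procedure.

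The authors deposited a table of FPKM values (fragments scaled for transcript length and library total) with 1 column per sample and 20133 genes, rounded to 2 decimals, per the file headers and the values themselves. Per the submitters' processing notes, HISAT2, RSEM and the mouse build GRCm38.p6 were used, with no versions or settings named. FPKM are not counts, so no count model was used and the number of reads per sample is not known. Relative depth was estimated from low values: in 24 genes whose few values above 0 lay within a ratio of 1.3 of each other, between 0.1 and 1 FPKM, the value taken as 1 read differed between samples by factors of 0.967 to 1.03. As these genes were kept for their agreement, the measure does not show that depth was equal, and the precision of low values per sample is not known. FPKM is a share of each library, so very abundant transcripts lower the values of other genes.

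Gene symbols were matched by gene identifier to the RefSeq annotation of GRCm38.p6, which held 20082 of the 20133 identifiers and supplied the coordinates. A spreadsheet program had turned 26 symbols into dates, and these were restored by identifier. The columns were matched to samples by name.

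Values were analysed as log2(FPKM + 1), so fold changes understate the change of low genes. Genes with at least 1 FPKM in at least 3 samples were kept, which left 14779. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. All 8 samples entered the fit, with no covariate. All changes are sh-Dlx3 minus control. Tested on simulated data with 200 of 14779 genes changed between 3 and 5 samples, the fit recovered 57% of genes changed 2-fold and 93% of those changed 4-fold, with 8 false calls among 158. The simulated noise was independent between genes, and only more abundant genes were changed. These rates therefore do not carry over to low genes or to samples that share tissue differences across many genes.

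Gene lists for cell types, pathways and handling were fixed before the data were examined: 40 lists with 822 entries, of which 787 matched a gene in the table. A list of mitochondrially encoded genes matched 0 entries and was not tested. The other 39, each with at least 5 members past the filter, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 39. Camera asks whether a list differs from the other genes. Camera with a correlation estimated for each list, and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Limma p-values of members were also adjusted by Benjamini-Hochberg over each list alone, with no correction for the number of lists. A list score per sample is the mean of log2(FPKM + 1) over members after subtracting each gene's mean over the 8 samples. Scores and Dlx3 were compared with two-sided exact permutation tests over all 56 assignments of 3 and 5 samples, whose smallest possible p is 0.0357. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for these tests and the plots.

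Genes were named by a rule fixed before the data were examined. It takes Dlx3 and, in each direction, the 12 genes with the largest change among those past the threshold, with at least 2 FPKM in the higher group, no overlap between the groups' values and an official name. Where fewer pass, the genes with the lowest p fill the places. As 0 genes passed, all 24 places were filled by p, and the conditions on level, overlap and name were applied to these as well. From each list described with examples, the 4 members with the lowest p were taken and, for cell types other than bone-forming cells, also the 2 most abundant; a few results that this rule selects are left out of the text. Which lists received examples was decided after the results were seen: those with a camera adjusted p under 0.001, and the Dlx, osteoclast, neutrophil and erythroid lists. Any other gene named was chosen after its values were seen.

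The comparison was repeated under 24 alternative settings, 20 of which were fixed before the data were examined: another pseudocount, other filters, other scalings, no trend, sample weights, the replicate number as a block, each sample left out in turn, other list tests, and a minimum fold change. The remaining 4, chosen after seeing the data, removed the pair of libraries lowest in olfactory neuron genes, used the olfactory or the erythroid list score as a covariate, or replaced camera by the permutation test of list scores. Short lists of nasal cell genes were also written after the data had been seen.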

Results

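RNA sequencing of alveolar bone was used to ask how inhibition of Dlx3, a homeobox transcription factor of craniofacial bone and teeth, alters gene expression while the socket heals. The table held 3 control and 5 sh-Dlx3 samples, collected 6 days after incisor extraction. Between 13698 and 14740 genes per sample reached 1 FPKM. Pairwise correlations of log2 values between samples ran from 0.883 to 0.988, so no sample was a copy of another. The highest were between sh-Dlx3 replicates 1 and 2 (0.988) and between replicates 3 and 4 (0.983). Control replicate 1 had a correlation of 0.978 with sh-Dlx3 replicate 3, above 0.914 and 0.971 with control replicates 2 and 3. The samples thus did not lie together by group alone.

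Dlx3 (gene identifier 13393, chromosome 11, 95120117 to 95125296 in GRCm38.p6) was detected in every sample. It measured 10.24, 7.64 and 8.27 FPKM in the controls and 8.71, 8.05, 6.47, 4.77 and 6.77 FPKM in sh-Dlx3 replicates 1 to 5. The means were 8.72 ± 1.36 FPKM (SD, n = 3) and 6.95 ± 1.53 FPKM (SD, n = 5), a difference of -20.2%. In 3 of the 5 sh-Dlx3 samples Dlx3 lay below every control. The difference was within the spread between samples: the log2 change was -0.30, with a standard error of 0.19 and a 95% interval of -0.73 to 0.12 (limma adjusted p = 0.456, two-sided exact permutation p = 0.179). Among the 7 tested members of the Dlx and Msx homeobox family, 0 passed the threshold, 0 did so adjusted over the list alone, and the list did not differ from other genes (camera adjusted p = 0.680, and adjusted p = 0.860 with an estimated correlation). Msx1 averaged 17.8 ± 3.24 FPKM (SD, n = 3) in controls and 13.1 ± 2.20 FPKM (SD, n = 5) in sh-Dlx3, Msx2 2.33 ± 0.98 and 3.32 ± 1.16 FPKM, and Dlx1 1.28 ± 0.54 and 0.91 ± 0.35 FPKM. The signs of Msx2 and Dlx1 flipped when the olfactory list score was a covariate.

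**Figure D1:**
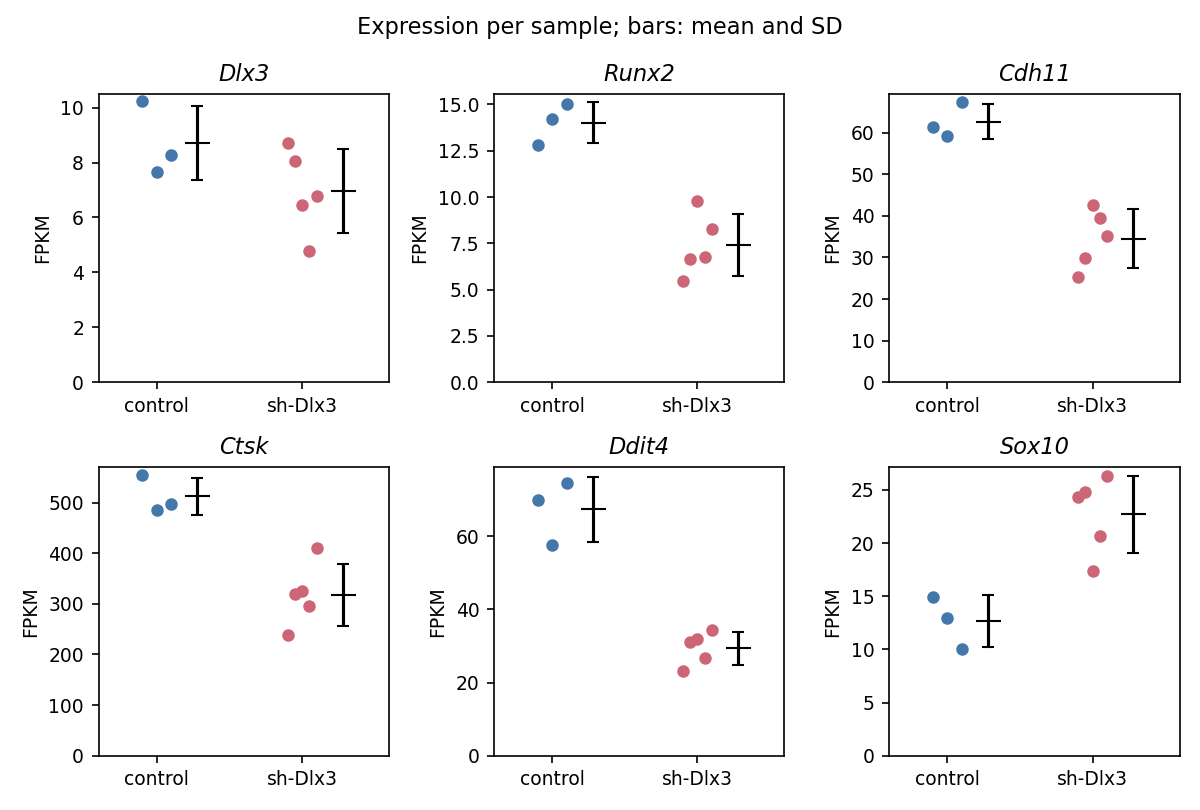
FPKM of 6 genes in each of the 3 control samples (blue) and 5 sh-Dlx3 samples (red), with the mean and SD of each group in black and each axis starting at 0. Dlx3 overlaps between the groups, from 7.64 to 10.24 FPKM in controls and from 4.77 to 8.71 FPKM in sh-Dlx3, while the other 5 genes do not overlap, although none passed the threshold over all genes.

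The genes with the lowest p were lower in sh-Dlx3, and they are of mixed function. Ddit4, a stress-induced inhibitor of mTOR signalling, averaged 67.4 ± 8.89 FPKM (SD, n = 3) in controls and 29.4 ± 4.48 FPKM (SD, n = 5) in sh-Dlx3. Errfi1, a feedback inhibitor of the EGF receptor, averaged 51.6 ± 2.93 and 25.3 ± 3.61 FPKM, and Gja1, the gap junction protein connexin 43 of osteoblasts and osteocytes, 88.1 ± 10.8 and 44.5 ± 4.91 FPKM. The laminin chain Lama3, the secreted factor Angptl2 and the heparan sulfatase Sulf1 had log2 changes of -1.13, -1.04 and -0.88, and Hif1a, the hypoxia-inducible transcription factor, -0.84. Ptgs2, the inducible prostaglandin synthase, and the phosphatase Dusp1 had log2 changes of -2.61 and -1.96, and the remaining lower genes of this group were the interleukin-7 receptor Il7r (-1.16), the chemokine receptor Ccr7 (-1.26) and the carbonic anhydrase Car13 (-0.79).

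Among genes with higher values in sh-Dlx3, the 12 with the lowest p were also of mixed function. Sox10, a transcription factor of Schwann cells and of several glands, averaged 12.6 ± 2.46 FPKM (SD, n = 3) in controls and 22.7 ± 3.64 FPKM (SD, n = 5) in sh-Dlx3. Elf5, an epithelial transcription factor, averaged 18.0 ± 3.14 and 27.7 ± 3.42 FPKM, the channel-activating protease Prss8 19.6 ± 3.74 and 29.8 ± 4.47 FPKM, and the mucosal peptide Tff1 11.3 ± 2.86 and 24.7 ± 8.69 FPKM. The interferon-inducible Ifi27l2a averaged 249 ± 12.8 and 398 ± 73.0 FPKM. Rsc1a1, Cracr2b, Pop5, Prr15l, Tpd52l1, Stard10 and Fam174b completed the 12, with log2 changes from 0.43 for Fam174b to 1.01 for Rsc1a1. In Fam174b, sh-Dlx3 replicate 3 stood apart from the rest of its group at 21.12 FPKM, still above every control.

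None of these genes passed the threshold. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p, 0.117, was shared by Ddit4, Errfi1, Lama3, Angptl2 and Gja1. At an unadjusted p under 0.05, 267 genes were higher and 2007 lower, against 739 in all by chance. Single samples moved these counts: 146 were higher and 794 lower without control replicate 3, 990 and 1644 without control replicate 1, 105 and 1941 without control replicate 2, and 648 and 1972 without sh-Dlx3 replicate 5. Without sh-Dlx3 replicate 1, 2 or 4, 168, 127 and 153 were higher and 1338, 1455 and 2034 lower. Without sh-Dlx3 replicate 3, 263 were higher and 2634 lower, the most lower genes of any single omission. The groups did not overlap in 121 higher and 1357 lower genes, 10% of those tested, against the 3.57% that chance gives; 6 of the 56 splits of the samples into 3 and 5, the real one included, gave at least these 1478 genes, the highest other split 3576. The median log2 change over all genes was -0.11. It was -0.35 when each sample was scaled to the same FPKM total and 0.01 with median-of-ratios scaling, under which 1460 genes were higher and 1648 lower at an unadjusted p under 0.05, so that the higher share moved from 11.7% to 47.0%. Without sh-Dlx3 replicate 5, 252 genes were lower and 2 higher at the threshold, and with the low-olfactory pair of libraries removed, control replicate 2 and sh-Dlx3 replicate 5, 77 were lower and 5 higher.

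**Figure D2:**
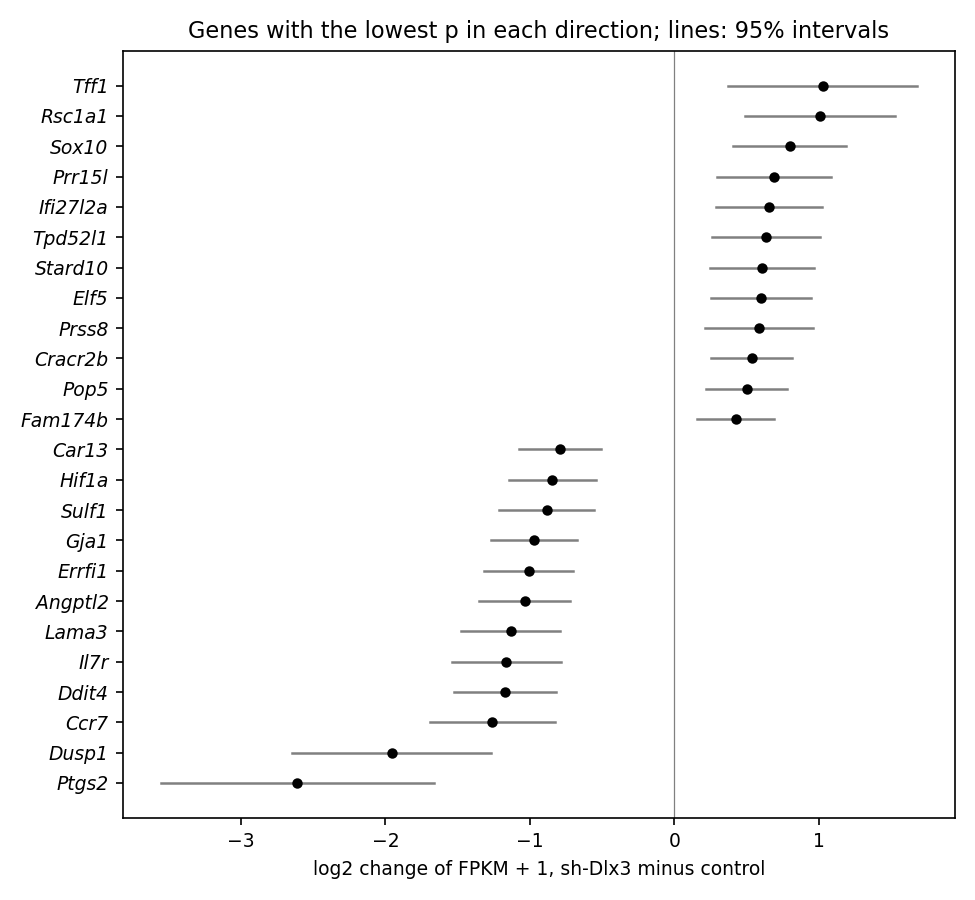
Log2 change of FPKM + 1, sh-Dlx3 minus control, of the 12 higher and 12 lower genes, as points with 95% intervals from limma (3 and 5 samples). The changes run from -2.61 for Ptgs2 to 1.03 for Tff1, and since these genes were picked by their p, the intervals do not allow for that choice.

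Taken list by list, genes of bone and connective tissue were lower in sh-Dlx3. Of the 39 lists, 19 were lower and 3 higher than other genes by camera with its preset correlation. With an estimated correlation 0 were called (lowest adjusted p = 0.496 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.0573). Also, 22 of the 56 ways to split the 8 samples into 3 and 5, the real one included, gave at least 22 called lists, and with the olfactory list score as a covariate, 0 lists were called lower, although medians such as -0.51 for osteoblasts and -0.71 for the ligament stayed below that of all genes, -0.35. Adjusted over each list alone, 147 of 724 list memberships passed, spread over 23 of the 39 lists, and 0 passed over all genes.

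The osteoblast and bone matrix list fell, with a median log2 change of -0.67 (camera adjusted p = 1.59e-07, and adjusted p = 0.496 with an estimated correlation). Of its 31 members, 27 had changes below 0, 22 passed adjusted over the list alone and 0 over all genes, and all 5 sh-Dlx3 samples scored below every control. Runx2, the master regulator of osteoblast differentiation, averaged 14.003 ± 1.11 FPKM (SD, n = 3) in controls and 7.39 ± 1.67 FPKM (SD, n = 5) in sh-Dlx3. The osteoblast cadherin Cdh11 averaged 62.7 ± 4.21 and 34.5 ± 7.06 FPKM and the collagen Col5a1 111 ± 29.5 and 50.8 ± 15.7 FPKM. The osteocyte list fell as well (median -0.69, camera adjusted p = 0.00044, and adjusted p = 0.496 with an estimated correlation), with 14 of 15 members below 0 and 6 past the threshold adjusted over the list alone. Its mineralization genes Dmp1 and Phex averaged 43.9 ± 4.74 and 10.6 ± 3.16 FPKM in controls and 17.2 ± 10.1 and 3.05 ± 2.69 FPKM in sh-Dlx3. The fall was uneven between samples. The osteocyte score was -0.81, -0.64 and -0.48 in sh-Dlx3 replicates 1, 2 and 5. In replicates 3 and 4 it was 0.29 and 0.09, nearer the controls, which ran from 0.40 to 0.59. The membrane protease Mmp14 averaged 195 ± 44.9 and 106 ± 25.1 FPKM, the hyaluronan receptor Cd44 45.3 ± 5.65 and 22.7 ± 7.54 FPKM, and Capg, the other most abundant member, 110 ± 11.6 and 91.0 ± 22.3 FPKM; the sign of Capg flipped with the olfactory covariate.

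Lists of bone resorption genes fell as well, but neither list score separated the groups. For osteoclasts and for osteoclastogenesis signals, 3 and 4 of the 5 sh-Dlx3 samples scored below every control (exact permutation p = 0.143 and 0.107, two-sided). The osteoclast list fell (median -0.34, camera adjusted p = 0.00544, and adjusted p = 0.667 with an estimated correlation), with 16 of 19 members below 0 and 0 past the threshold adjusted over the list alone; this call was lost with a stricter expression filter (adjusted p = 0.0672). Ctsk, the collagen-degrading protease of osteoclasts, averaged 512 ± 37.2 FPKM (SD, n = 3) in controls and 318 ± 61.9 FPKM (SD, n = 5) in sh-Dlx3, and Mmp9 182 ± 16.7 and 102 ± 37.7 FPKM. The proton pump subunit Atp6v0d2 and the fusion factor Ocstamp had log2 changes of -0.48 and -0.68, whereas Ckb, the second most abundant member, had one of 0.58 that was 0.21 without control replicate 2 and 0.92 without control replicate 1, and flipped with the olfactory covariate. The list of osteoclastogenesis signals fell with a median of -0.54 (camera adjusted p = 0.000468, and adjusted p = 0.496 with an estimated correlation), with 13 of 14 members below 0 and 6 past the threshold adjusted over the list alone. Csf1, a growth factor that osteoclast precursors need, averaged 20.6 ± 1.499 and 14.2 ± 2.08 FPKM, and Wnt5a and its receptor Ror2 had log2 changes of -0.57 and -0.47. In Ror2, sh-Dlx3 replicate 1 lay apart at 2.12 FPKM.

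Lists of fibroblast and scar matrix, periodontal ligament and tendon, and matrix-degrading proteases fell, with medians of -1.05, -0.76 and -0.81. Their camera adjusted p were 6.08e-09, 1.41e-05 and 6.08e-09, and each had adjusted p = 0.496 with an estimated correlation. All 22, 15 and 22 members had changes below 0, and 17, 7 and 15 passed adjusted over the list alone. The fibrillar collagen genes Col1a1 and Col1a2 averaged 2733 ± 684 and 2835 ± 677 FPKM (SD, n = 3) in controls and 1280 ± 458 and 1317 ± 513 FPKM (SD, n = 5) in sh-Dlx3. The matricellular gene Ccn1 averaged 37.2 ± 6.17 and 17.8 ± 3.52 FPKM, and Loxl2, Fbn1 and Lrrc15 had log2 changes of -1.16, -1.46 and -1.06. In the ligament list, Col12a1 averaged 94.0 ± 16.5 and 34.6 ± 11.5 FPKM, the proteoglycan genes Lum and Dcn 400 ± 59.9 and 199 ± 38.7 FPKM, and 621 ± 157 and 345 ± 103 FPKM, and Postn 434 ± 33.8 and 238 ± 92.9 FPKM; Aspn and Tnc had log2 changes of -0.97 and -0.79. Among the proteases, the gelatinase Mmp2 averaged 297 ± 66.5 and 150 ± 28.4 FPKM, and Adamts12, Adamts2 and the inhibitor Timp2 had log2 changes of -1.27, -1.01 and -0.77.

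Signalling and vascular lists fell as well. The BMP and TGF-beta list had a median of -0.42 and the endothelium and angiogenesis list one of -0.53, with camera adjusted p of 0.000163 and 2.47e-07 and, for both, adjusted p = 0.496 with an estimated correlation. Changes were below 0 in 25 of 29 and 22 of 22 members, and 10 and 14 passed adjusted over the list alone. The BMP antagonist Grem1 averaged 5.91 ± 0.93 FPKM (SD, n = 3) in controls and 1.38 ± 0.93 FPKM (SD, n = 5) in sh-Dlx3, and Inhba, Skil and Ltbp2 had log2 changes of -1.02, -0.74 and -0.49. Cdh5, the endothelial cadherin, averaged 27.8 ± 5.36 and 15.4 ± 2.73 FPKM, the fenestral protein gene Plvap 68.7 ± 13.4 and 43.4 ± 8.80 FPKM and Egfl7 39.1 ± 6.90 and 32.0 ± 7.67 FPKM. The VEGF receptors Kdr and Flt1 had log2 changes of -0.58 and -0.59, and Aplnr one of -1.05. The endothelial score of sh-Dlx3 replicate 1, -0.52, lay apart from its group.

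Inflammatory genes were low in 4 of the 5 sh-Dlx3 samples and at control level in the other. Il1b, interleukin-1 beta, averaged 311 ± 33.8 FPKM (SD, n = 3) in controls and measured 25.39, 5.37, 13.93 and 24.77 FPKM in sh-Dlx3 replicates 1 to 4, but 280.8 FPKM in replicate 5. Il1a likewise measured 1.18 to 2.24 FPKM in 4 samples and 13.37 FPKM in replicate 5, against 13.9 ± 1.08 FPKM (SD, n = 3) in controls. The list of inflammatory cytokines and chemokines fell with a median of -1.31 (camera adjusted p = 0.000312, and adjusted p = 0.667 with an estimated correlation), with 21 of 23 members below 0 and 1 past the threshold adjusted over the list alone; Il1rn, the interleukin-1 receptor antagonist, had a log2 change of -2.07. The score of replicate 5 was 1.37, above every control. With the olfactory covariate its median was -0.24, less negative than that of all genes, -0.35, and camera called it in the opposite direction.

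The list of immediate early and heat shock genes, which respond to handling as well as to growth signals, fell with a median of -0.57 (camera adjusted p = 0.000312, and adjusted p = 0.496 with an estimated correlation), with 17 of 20 members below 0 and 10 past the threshold adjusted over the list alone. With the olfactory covariate its median was -0.20, less negative than that of all genes, and the call was lost (adjusted p = 0.404). Fos averaged 19.1 ± 2.32 FPKM (SD, n = 3) in controls and 8.11 ± 4.17 FPKM (SD, n = 5) in sh-Dlx3, where replicate 5 lay apart at 15.55 FPKM, as it did for Dusp1 at 48.98 FPKM. Btg2 and Egr1 had log2 changes of -0.73 and -0.80. The macrophage and monocyte list fell as well (median -0.68, and -0.45 without sh-Dlx3 replicate 1; camera adjusted p = 0.00044, and adjusted p = 0.595 with an estimated correlation), with 19 of 20 members below 0 and 7 past the threshold adjusted over the list alone. Cd68 averaged 77.9 ± 10.04 and 47.1 ± 8.90 FPKM, Csf1r, the receptor for Csf1, 54.3 ± 7.43 and 32.5 ± 10.04 FPKM, and Arg1 had a log2 change of -2.39. The most abundant members, Lyz2 and Apoe, had log2 changes of 0.14 and -0.16, and their signs flipped, that of Lyz2 with scaling to equal totals and with sample weights and that of Apoe with the olfactory covariate.

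Surface and nasal epithelium moved in opposite directions. The epithelium and gingiva list fell (median -1.02, camera adjusted p = 1.75e-05, and adjusted p = 0.496 with an estimated correlation), with 24 of 26 members below 0 and 5 past the threshold adjusted over the list alone, a call that was lost without control replicate 2 (median -0.59, adjusted p = 0.0652). The basal keratin Krt5 averaged 271 ± 36.3 FPKM (SD, n = 3) in controls and 180 ± 28.6 FPKM (SD, n = 5) in sh-Dlx3, Krt15 290 ± 41.6 and 226 ± 28.2 FPKM, and the wound keratins Krt6a and Krt6b had log2 changes of -1.24 and -1.05. The desmosomal cadherin Dsg3 and the basal-cell factor Trp63 had log2 changes of -1.35 and -0.58. The olfactory and respiratory epithelium list and the salivary and mucous gland list rose, with medians of 1.32 and 1.17 (camera adjusted p = 2.82e-08 and 1.59e-07, and for both adjusted p = 0.496 with an estimated correlation). Changes were above 0 in 14 of 15 and 10 of 11 members, 0 members passed adjusted over either list alone, and 4 of 5 sh-Dlx3 samples scored above every control. The medians depended on single libraries: without control replicate 2 they were 0.48 and 0.53, and over all single omissions they ran from 0.48 to 1.98 and from 0.53 to 1.23, with both lists called each time.

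Genes of odorant-binding proteins, secreted lipocalins of the nose, were among the most abundant in each of the 8 samples. Obp1a averaged 37666 ± 23856 FPKM (SD, n = 3) in controls and 62481 ± 26451 FPKM (SD, n = 5) in sh-Dlx3, and Obp2a 19478 ± 2947 and 34991 ± 12552 FPKM. The 10 most abundant genes held 19.1 to 53.2% of all FPKM in a sample. Omp, the marker of mature olfactory neurons, measured 446.49, 11.9 and 126.71 FPKM in the controls and 460.34 to 700.12 FPKM in 4 sh-Dlx3 samples, with replicate 5 apart at 123.86 FPKM. The cilium gene Tekt1 had a log2 change of 0.80, and 0.28 without control replicate 2. The secreted Bpifb9a measured 82.68, 9629.52 and 2.4 FPKM in the controls and 1805.06 to 6039.86 FPKM in sh-Dlx3, so its log2 change of 4.68 rests on single libraries: it was 1.99 without control replicate 3 and 7.73 without control replicate 2. Among gland genes, the water channel Aqp5 averaged 162 ± 36.1 and 248 ± 43.5 FPKM, Pip 155 ± 95.7 and 341 ± 166 FPKM, and Dcpp3 105 ± 127 and 733 ± 630 FPKM, while Cldn10, Krt18 and Krt8 had log2 changes of 0.59, 0.63 and 0.60, and 0.37, 0.33 and 0.28 without control replicate 2. The olfactory score averaged -0.88 ± 1.01 (SD, n = 3) in controls and 0.53 ± 0.58 (SD, n = 5) in sh-Dlx3 (exact permutation p = 0.0714, two-sided; adjusted p = 0.186), and the groups overlapped, with control replicate 1 at 0.15 and sh-Dlx3 replicate 5 at -0.50.

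**Figure D3:**
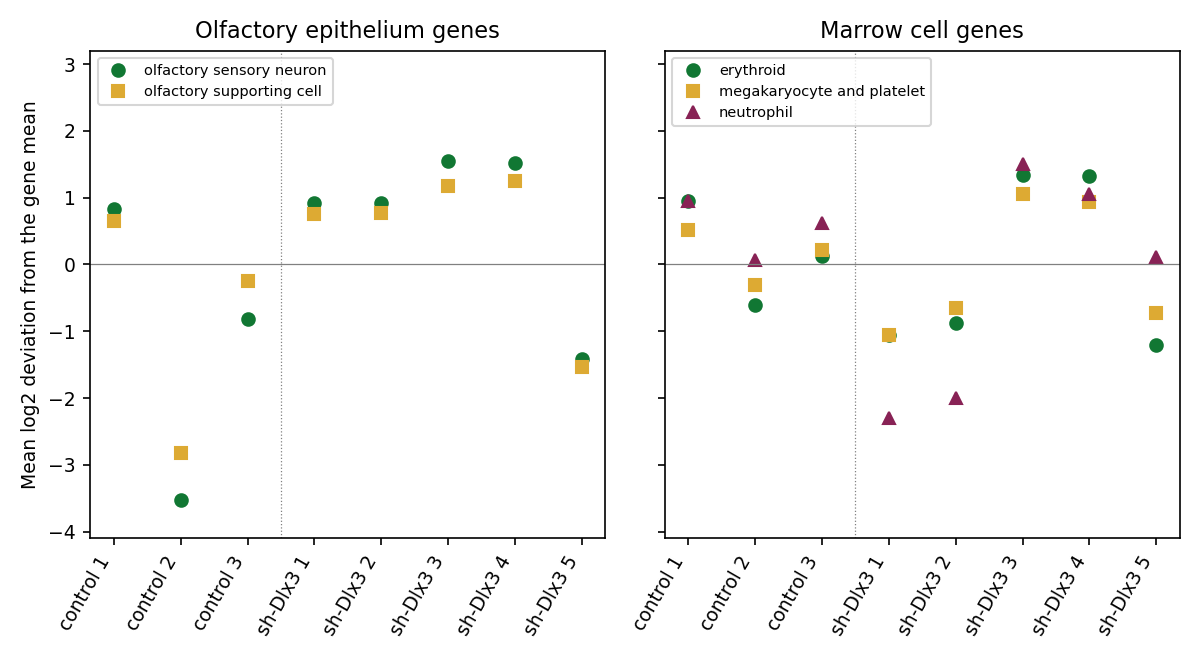
Scores of olfactory neuron and supporting cell genes and of erythroid, megakaryocyte and neutrophil genes in each of the 3 control and 5 sh-Dlx3 samples, as mean log2 deviations. Colours and symbols mark the gene lists, and a dotted vertical line parts the control from the sh-Dlx3 samples. The olfactory neuron score runs from -3.53 in control replicate 2 to 1.56 in sh-Dlx3 replicate 3, and the erythroid score from -1.21 in sh-Dlx3 replicate 5 to 1.34 in replicate 3.

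**Figure D4:**
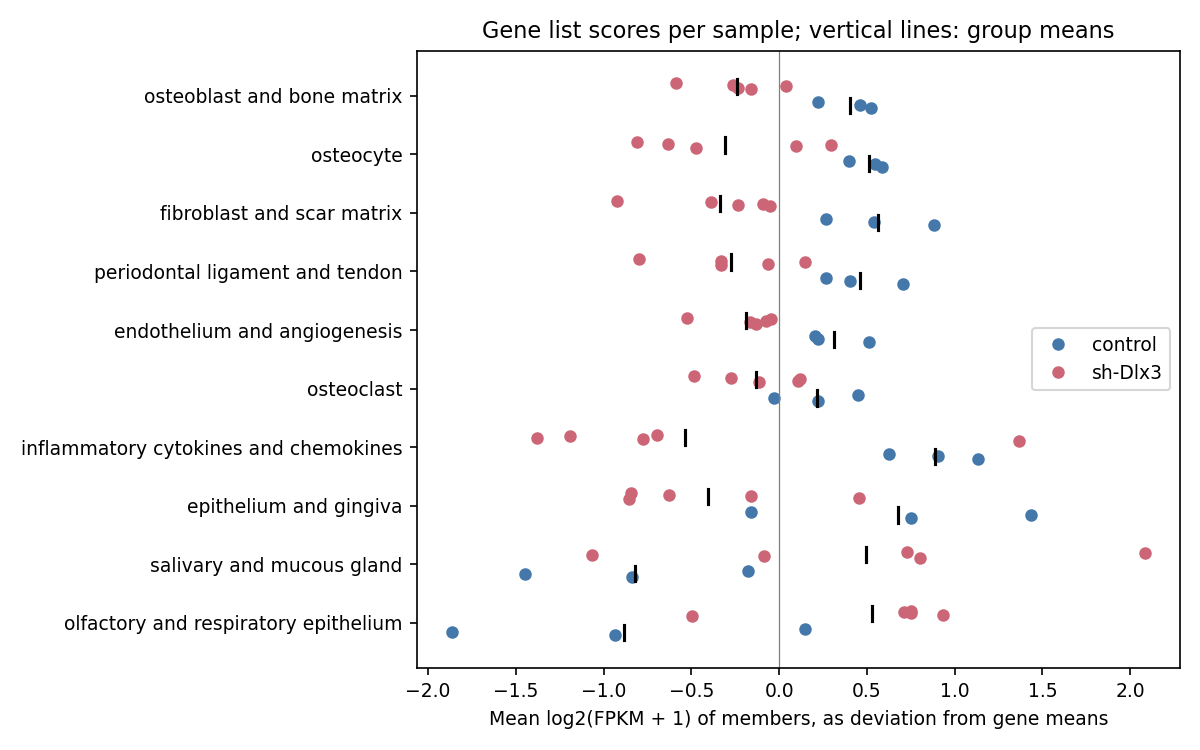
Scores of 10 of the 39 lists, as the mean log2 deviation of their members from each gene's mean, for each control (blue) and sh-Dlx3 sample (red), with vertical lines at the group means. In the fibroblast, osteoblast, osteocyte, ligament and endothelial lists all 5 sh-Dlx3 samples lie below the 3 controls, while the inflammatory score of sh-Dlx3 replicate 5 lies at 1.37, above every control.

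Neutrophil and erythroid genes varied widely within the sh-Dlx3 group. Their lists were not called (camera adjusted p = 0.559 and 0.680, and adjusted p = 0.926 and 0.959 with an estimated correlation), and 0 members of either passed adjusted over the list alone. The neutrophil score was -2.30 and -1.99 in sh-Dlx3 replicates 1 and 2 but 1.502 and 1.05 in replicates 3 and 4, and the median and mean of the erythroid list, -0.24 and -0.25, had the opposite sign to its camera direction. The neutrophil gene S100a8 averaged 4320 ± 528 FPKM (SD, n = 3) in controls and 4019 ± 3473 FPKM (SD, n = 5) in sh-Dlx3. Ngp averaged 357 ± 228 and 377 ± 501 FPKM, and Ltf 3266 ± 1102 and 4232 ± 1765 FPKM. The sign of the change of Ltf flipped under quantile normalization and sample weights and without the low-olfactory pair. The receptors Csf3r, Il1r2 and Cxcr2 had log2 changes of -1.65, -1.67 and -1.35. The globin genes Hba-a1, Hba-a2 and Hbb-bs, which belong to families of near-identical copies and are therefore uncertain, had log2 changes of -0.53, -0.53 and -0.56, and -0.22, -0.23 and -0.24 without sh-Dlx3 replicate 5. The transferrin receptor Tfrc had one of -0.35, and -0.20 without control replicate 1.

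Of the remaining lists, Wnt ligands and antagonists (median -0.43, camera adjusted p = 0.00774) and mesenchymal progenitor and marrow stroma (-0.36, 0.0102) also fell, both with adjusted p = 0.496 with an estimated correlation, and so did mast cells, basophils and eosinophils (-0.81, 0.0124), chondrocytes (-0.76, 0.0138), T and NK lymphocytes (-0.36, 0.0393) and the cell cycle (-0.39, 0.0433), with adjusted p = 0.667, 0.722, 0.667 and 0.827 with an estimated correlation. The histone list rose (0.28, 0.00919), with adjusted p = 0.496 with an estimated correlation. Its median was 0.14 without sh-Dlx3 replicate 2 or 5 and 0.16 without control replicate 3, and that of the cell cycle was -0.21 without sh-Dlx3 replicate 1. The cell cycle score of sh-Dlx3 replicates 3 and 4, 0.48 and 0.43, lay above every control, as their erythroid scores did, and 0 of its 28 members had an unadjusted p under 0.05. Adjusted over the list alone, 6, 7, 0, 1, 2, 0 and 1 members of these 7 lists passed. Calls of the last 5 were lost when single samples were left out: mast cells without control replicate 2, chondrocytes without control replicate 2 or sh-Dlx3 replicate 5, and lymphocytes, the cell cycle and histones in 3 or more such fits. The 17 lists not called included oxidative phosphorylation, cytosolic ribosomal proteins and the interferon response, with medians of -0.01, -0.01 and -0.07.

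By sample, 11 of the 39 list scores separated all 5 sh-Dlx3 samples from all 3 controls. Each had an exact permutation p of 0.0357, the smallest that 56 assignments allow, and an adjusted p of 0.127, so 0 lists passed the threshold in this test. With this smallest p, a list could pass after adjustment only if most of the 39 lists separated the groups fully. The lack of calls here therefore decides little.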

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

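Among the 5 sh-Dlx3 samples, single samples stood far from the rest in 9 results, and in 6 of these it was replicate 5. The gap to the nearest other sample exceeded 0.71 of the group's range in each. Of 151 results tested, 39 list scores, 110 genes and 2 others, 7.55 would show such a gap by chance, 1 in 20. The number is thus near chance. The 6 with replicate 5 are not independent, as Omp and Il1a belong to lists also counted and Fos and Dusp1 share a list, and their concentration was not tested. The tests in this part were chosen only after the result was seen, apart from this gap rule.

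Inflammatory and early-response genes in replicate 5 were nearer control level. Its inflammatory score was 1.37, against -1.38 to -0.69 in the other 4 samples. Interleukin gene Il1a measured 13.37 FPKM against 1.18 to 2.24 FPKM, Fos 15.55 against 5.84 to 6.74 FPKM, and Dusp1 48.98 against 16.65 to 21.64 FPKM. Its olfactory list score was -0.50 against 0.71 to 0.93, and Omp, the olfactory neuron marker, 123.86 against 460.34 to 700.12 FPKM. In replicate 1 the endothelial score was -0.52 against -0.17 to -0.04, and the Wnt5a receptor Ror2 measured 2.12 against 2.77 to 3.06 FPKM. In replicate 3, Fam174b measured 21.12 against 23.74 to 24.64 FPKM.

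Nasal transcripts are a pattern of the whole series. The olfactory neuron and supporting cell scores, from 15 genes of which 6 are also in the olfactory list, had a Pearson r of 0.9887 over the 8 samples (exact permutation p = 9.92e-05, two-sided; adjusted over 4 correlations p = 0.000248), and 0.994 without control replicate 2 and sh-Dlx3 replicate 5. Genes of 2 cell types that share the olfactory epithelium thus rise and fall together, and a candidate source is nasal lining taken with the bone. No bone-only reference was used here. The score of 7 nasal gland secretion genes, Obp1a among them, did not follow these scores throughout. It was 0.28 in control replicate 2, lowest in the neuron score at -3.53, and -0.81 in control replicate 1, at 0.84. In sh-Dlx3 replicate 1 both were high, at 0.99 and 0.92. The neuron and supporting cell scores thus do not stand for all nasal transcripts. Odorant receptor genes with at least 1 FPKM numbered 146, 3 and 25 in the controls and 127, 137, 213, 192 and 3 in sh-Dlx3. As the controls carried these transcripts too, inhibition of Dlx3 does not account for their presence; an effect on their amount stays open.

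At an adjusted p under 0.05 the real count was 0 genes (limma; 2274 at an unadjusted p under 0.05), so all 56 of 56 splits of the samples into 3 and 5 necessarily gave as many, which tests nothing. The highest other split gave 2257, for sh-Dlx3 replicates 1, 2 and 5 against the rest, which points to a structure of the samples. For the next 2 counts chance could not be excluded. At an unadjusted p under 0.05, 7 of 56 gave at least the real 2274, with 5474 for control replicate 2 and sh-Dlx3 replicates 1 and 5. For lists, 22 of 56 gave at least the real 22, with 29 for control replicate 1 and sh-Dlx3 replicates 1 and 2.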

How the results depend on the processing

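Lower bone, matrix and vascular genes kept their direction in most settings, but counts of genes and calls of lists did not. The 2 covariates, the removal of both low-olfactory libraries and the exact permutation of list scores were chosen after seeing the data. The direction of a list is the sign of its median, also a later choice, except that opposite camera calls count as reversed; camera directions changed in 15 lists, 7 of them called, with the olfactory covariate. Over the alternatives 48 list results reversed, 89 called ones were lost, 28 were gained and 687 stayed; for named genes 11 reversed, 213 were gained and 1946 stayed. The causes were not tested. Absolute depth is unknown, so the precision of low genes is too. Dlx3 had a log2 change of -0.55 to -0.15 (adjusted p = 0.152 to 0.842).

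On the TPM scale 2 genes were lower, Dusp1 and Ptgs2, and medians were -0.165 for Dlx and Msx homeobox family, -0.226 for nerve and Schwann cell and -0.197 for endoplasmic reticulum stress; Lyz2 had -0.124. With median-of-ratios scaling they were 0.0620 for interferon response, 0.0157 for hypoxia and glycolysis, 0.131 for oxidative phosphorylation and 0.129 for cytosolic ribosomal proteins. With quantile normalization they were 0.0628 for interferon response and 0.0327 for oxidative phosphorylation, and Ltf had -0.447. With sample quality weights, whose estimation did not converge and which gave control replicate 3 a weight of 28.8, 1215 genes were higher, 5699 lower and 5 lists higher; nerve and Schwann cell had -0.0126, Ltf -0.00109 and Lyz2 -0.0432.

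With the replicate block 249 genes were higher and 806 lower, skeletal muscle had 0.129 and oxidative phosphorylation 0.0562, and the neutrophil (-1.36, adjusted p = 1.0e-08) and adipocyte (-0.758, adjusted p = 0.00838) lists gained calls. Numbers 4 and 5 exist only in sh-Dlx3, so the group difference in this fit rests on replicates 1 to 3 of each group. It is not a result of all 8 samples. Whether the numbers pair the samples is not known, however, as the labels do not state it. Deviations of samples with the same number had correlations of 0.346, -0.0265 and 0.0664, and 1 of 3 controls matched its own number best. Tissue differences between samples also enter these deviations, so low correlations do not exclude pairing. Camera with an estimated correlation, fry and the exact permutation of list scores gave 0 lists higher and 0 lower. The permutation could hardly have called a list, given its smallest possible p.

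With both low-olfactory libraries removed, control replicate 2 and sh-Dlx3 replicate 5, 5 genes were higher and 77 lower; Dlx and Msx homeobox family had -0.111, nerve and Schwann cell -0.00698, endoplasmic reticulum stress -0.0534 and Ltf -0.161. With the olfactory score covariate 8 lists were higher and 0 lower. Medians were -0.330 for Dlx and Msx homeobox family, 0.0146 for T and NK lymphocyte, 0.0647 for skeletal muscle, -0.424 for nerve and Schwann cell, 0.254 for interferon response, -0.241 for inflammatory cytokines and chemokines and 0.216 for cytosolic ribosomal proteins. Capg had 0.108, Ckb -0.341, Msx2 -0.330, Dlx1 0.0840, Apoe 0.113 and Omp -0.893. With the erythroid score covariate megakaryocyte and platelet had 0.0754.

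Leaving out each sample in turn gave 0 to 2 genes higher and 0 to 252 lower, the highest of both without sh-Dlx3 replicate 5, and 2 to 7 lists higher, 7 without control replicate 2 and 6 without sh-Dlx3 replicate 3 or 4. Medians ran from -0.131 to 0.337 for Dlx and Msx homeobox family, -0.379 to 0.156 for B lymphocyte and plasma cell, -0.758 to 0.233 for erythroid, -0.568 to 0.102 for megakaryocyte and platelet, -0.180 to 0.122 for nerve and Schwann cell, -0.0508 to 0.0470 for oxidative phosphorylation, -0.0689 to 0.0568 for cytosolic ribosomal proteins and -0.0454 to 0.125 for endoplasmic reticulum stress. Epithelium and gingiva lost its call without control replicate 2 (adjusted p = 0.0652).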

Other observations

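Blood-forming marrow, enamel and cartilage genes varied widely between samples of the same group. All genes named in this part, and all its tests, were chosen only after the result was seen. Elane, a neutrophil precursor protease, measured 56.1, 18.2 and 34.0 FPKM in the controls and 0.71, 2.76, 171, 116 and 1.81 FPKM in sh-Dlx3 replicates 1 to 5. Slc4a1, the red cell anion exchanger, measured 25.5, 1.91 and 7.61 FPKM and 0.48, 0.71, 34.7, 37.4 and 0.39 FPKM. The enamel matrix gene Amelx measured 153.67, 5.51 and 97.2 FPKM and 346.71, 172.94, 1.87, 0 and 2.03 FPKM. The cartilage collagen Col2a1 measured 21.8, 20.7 and 25.6 FPKM and 1.44, 2.35, 15.7, 28.6 and 0.77 FPKM, and Sost, the Wnt inhibitor of osteocytes, 11.01, 14.5 and 9.44 FPKM and 0.20, 0.31, 15.4, 10.6 and 0.19 FPKM.

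For the marrow pattern, a difference in sequencing depth would not shift abundant genes, since FPKM are scaled to the library total. Hba-a1 measured 614.6 to 1203.65 FPKM in sh-Dlx3 replicates 1, 2 and 5, and 3106.87 and 3041.89 FPKM in replicates 3 and 4. S100a8 measured 434.25 and 391.43 FPKM in replicates 1 and 2, and 4661.41 to 7646.63 FPKM in replicates 3 to 5. These values argue against depth for these abundant genes, while Ltf, also abundant, did not follow S100a8. For low genes depth stays open. The highest relative depth was 1.067 times the lowest, but the genes used were kept for agreeing between samples, so this decides nothing. Different amounts of marrow in the pieces taken are a candidate explanation: the erythroid and megakaryocyte scores, from 19 and 14 genes that share 0, had a Pearson r of 0.9805 over the 8 samples (exact permutation p = 0.000124, two-sided; adjusted over 4 correlations p = 0.000248) and 0.955 without sh-Dlx3 replicates 3 and 4. The erythroid score and the osteoblast score had r of 0.272 (exact permutation p = 0.499, two-sided), and 0.621 without sh-Dlx3 replicates 3 and 4. A link between marrow content and the osteoblast score thus stays open. A response to Dlx3 inhibition that differs between samples was not tested.

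The lower bone and fibroblast matrix genes, 51 members of 2 lists, had a median log2 change of -0.78. With median-of-ratios scaling, which brings the median of all genes to 0.01, it was -0.65, and -0.88 to -0.50 with each sample left out, which argues against a few abundant secretory transcripts as the whole cause. With the olfactory list score as a covariate it was -0.58, against -0.35 for all genes, and neither list kept its call. With both low-olfactory libraries removed instead, both lists kept their call by camera with its preset correlation. In the samples left, however, the olfactory list score was 0.15 and -0.93 in controls and 0.71 to 0.93 in sh-Dlx3. As the removal left the groups apart in this score, the kept calls do not separate the explanations. The olfactory neuron and osteoblast scores had r of -0.567 (exact permutation p = 0.141, two-sided), and -0.629 without control replicate 2 and sh-Dlx3 replicate 5. Nasal tissue and Dlx3 inhibition cannot be told apart as explanations of these genes, since the olfactory score was unevenly spread over the groups, without a difference past the threshold (exact permutation p = 0.0714, two-sided), and 8 samples are few for a covariate.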
